A study of Homo sapiens with 6 samples.

How the data were processed

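Total RNA of PC3 cells and a commercial RNA preparation of normal prostate epithelial cells were labelled with Cy3 as cRNA and hybridised to one-colour Agilent arrays, per the labels' protocols. Each group held 3 samples, and groups and replicate numbers were taken from the sample titles. Growth conditions are stated alike for all samples in the labels, although the epithelial RNA was bought. Agilent Feature Extraction 10.7.3.1 and limma are named in the submitters' processing notes, without a role. Background correction, scaling, averaging of spots and the filter on features are not given in the sources used here.

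The values analysed were the log2 intensities in the authors' deposited value table, with 1 column per sample and 1 row per feature number. Scale and normalization were read from the values. They run from 5.67 to 16.001, and the quantiles of the 6 columns coincide closely, as after quantile normalization between arrays. The values do not look centred by gene, since features differ widely in level, and each column holds the signal of 1 sample, so no ratio direction had to be settled. The table holds 78372 features with numbers up to 105068, so a part of the array was removed before deposit. Scanner files were not analysed here, so control features, detection flags and saturation could not be used, and every feature in the table entered the fit. The number of arrays limits the precision of every value.

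Feature numbers were not paired with probes or genes in the sources used here. The reference table of human genes has no feature numbers and was not used. For this reason the gene-level fit, the comparison of name classes and the tests of 20 gene lists, all fixed before the data were examined, were not run. The rule for named genes provided for features without a symbol, at most 2 per direction by size of the difference among those with an adjusted p under 0.05 and no overlap between the arrays of the groups. It also excluded some genes by name, and since that exclusion cannot be applied to unnamed features, no single feature that is bright in epithelial cells and near the floor in PC3 is reported, and 2 features higher in PC3 are.

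Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend on the 6 arrays, without a block. P-values are two-sided and Benjamini-Hochberg adjusted over all features, at a threshold of 0.05. A change of 2-fold is an absolute log2 difference of at least 1. The pipeline was tested on simulated data with the real features' means and spreads, 78372 in all, of which 200 were changed in the comparison of PC3 with epithelial cells. It called 14% of those changed by 0.25 log2 units, 58% of those changed by 0.5, 96% of those changed by 1 and 100% of those changed by 2, and it called 10 unchanged features. The changed features were drawn from those with a mean above 7, and the simulated noise was independent between features. With so few changed features the adjustment is stricter than in the real comparison. These rates therefore check the code and do not measure the power or the false calls of that comparison.

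Replicate numbers are shared by the groups, but nothing in the labels ties a numbered PC3 sample to the epithelial sample of that number. Deviations from the group means correlated across features by 0.075, 0.095 and 0.056 for the pairs of equal number, and by -0.15 to 0.075 for the other pairs. These values do not settle whether the numbers pair the samples. As the labels give no pairing, the numbers were not used in the fit, and a block on them was run as an alternative. Alternatives fixed before the data were examined were the replicate block, quantile normalization of the deposited values, centring on the median or the 75th percentile, leaving out the dimmest features by a fixed share of 33.3%, eBayes without a trend or with robust hyperparameters, array weights, and leaving out each array in turn. Alternatives added after the data had been examined were the subtraction of the 1st percentile of each array on the linear scale with a floor of 16 units, limma's treat at 1.2-fold, other levels for bright and near-floor features, and subtraction of the mean of neighbouring dim features. All sample titles carry the tag set 1, which the arrays share and which therefore parts none of them. No batch, slide or scan was given in the labels, so batches could not be examined.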

Results

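Total RNA of prostate cells was measured on 6 one-colour microarrays deposited as noncoding RNA profiling, 3 of PC3 and 3 of normal prostate epithelial cells. PC3 is an established prostate cancer line that grows without androgen, and the epithelial RNA was a commercial preparation. The study's design describes 3 independent experiments, and its title names long noncoding RNA as the object and detection of prostate cancer as the purpose. Each array gave a log2 intensity for the same 78372 features, identified only by feature numbers between 4 and 105068. No gene name was paired with a feature number in the sources used here, so the 20 gene lists fixed in advance were not tested and the results below describe groups of features.

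Signal on the 6 arrays covered nearly the same range. The median log2 intensity lay between 6.795 and 6.796 on every array, the 95th percentile lay between 10.40 on PC3 replicate 1 and 10.41 on epithelial replicate 1, and the maximum was 16.001. Most features were dim. Over the 6 arrays 56.3% of the features had a mean under 6.9, against a 1st percentile of 6.55 on every array, so most of the features lay within a narrow band at the lower end of the scale. A feature in that band has no interpretable level of its own, because detection flags were not analysed here.

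Arrays of one cell type resembled each other far more than arrays of different cell types. Across features, Pearson's r was between 0.9952 and 0.9981 for the PC3 pairs and between 0.9955 and 0.9971 for the epithelial pairs. It was between 0.9187 and 0.9205 for pairs of a PC3 and an epithelial array. These coefficients are taken across features, which are not independent replicates. The first principal component, which parted the PC3 from the epithelial arrays, held 94.1% of the variance. Between arrays of one group, 6 to 171 features differed at least 2-fold, and between arrays of the 2 groups 4762 to 4998 did. The highest count within a group, 171 features, was between PC3 replicates 1 and 3, and PC3 replicate 3 lay apart from the other PC3 arrays on the second component, which held 2.28% of the variance. The median standard deviation of a feature was 0.033 log2 units among the PC3 arrays and 0.040 among the epithelial arrays (n = 3 each). Nothing in the labels says that the epithelial replicates came from separate donors or cultures, so for that group the spread may be technical and the p-values measure only the spread between these arrays.

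The comparison asked which transcripts differ between PC3, a prostate cancer line, and purchased RNA of normal prostate epithelial cells. The groups differ in the source of the RNA as well as in cell type, and these cannot be told apart. No other cancer line was among these samples, so the differences are those of PC3 and not of prostate cancer in general. A large part of the measured features differed, in both directions in nearly equal numbers. In limma's moderated test with Benjamini-Hochberg adjustment over all features, 30534 features passed an adjusted p of 0.05, which is 39.0% of those measured. Of these, 15023 were higher and 15511 were lower in PC3. Most of the differences were small. The median change was 0.37 on the log2 scale among features higher in PC3 and -0.38 among those lower. At least 2-fold changes were found for 4802 features, of which 2448 were higher and 2354 lower in PC3. In 30299 of the 30534 features the 3 PC3 arrays did not overlap the 3 epithelial arrays, and 47.7% of all features showed such a separation where chance alone gives 10% for 3 arrays against 3.

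Large changes were rare and also occurred in both directions. At least 4-fold differences were found for 557 features higher and 471 lower in PC3. At least 16-fold differences were found for 46 higher and 66 lower, and at least 64-fold differences for 12 higher and 12 lower. The largest increase in PC3 was 8.32 on the log2 scale and the largest decrease was -8.30. Both are differences from a group near the floor, and after subtraction of the 1st percentile of each array they were 10.42 and -10.85. Because all arrays had been brought to nearly the same distribution before deposit, the near balance of higher and lower features is partly fixed by that step and is not a measure of total RNA in either cell type.

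**Figure D1:**
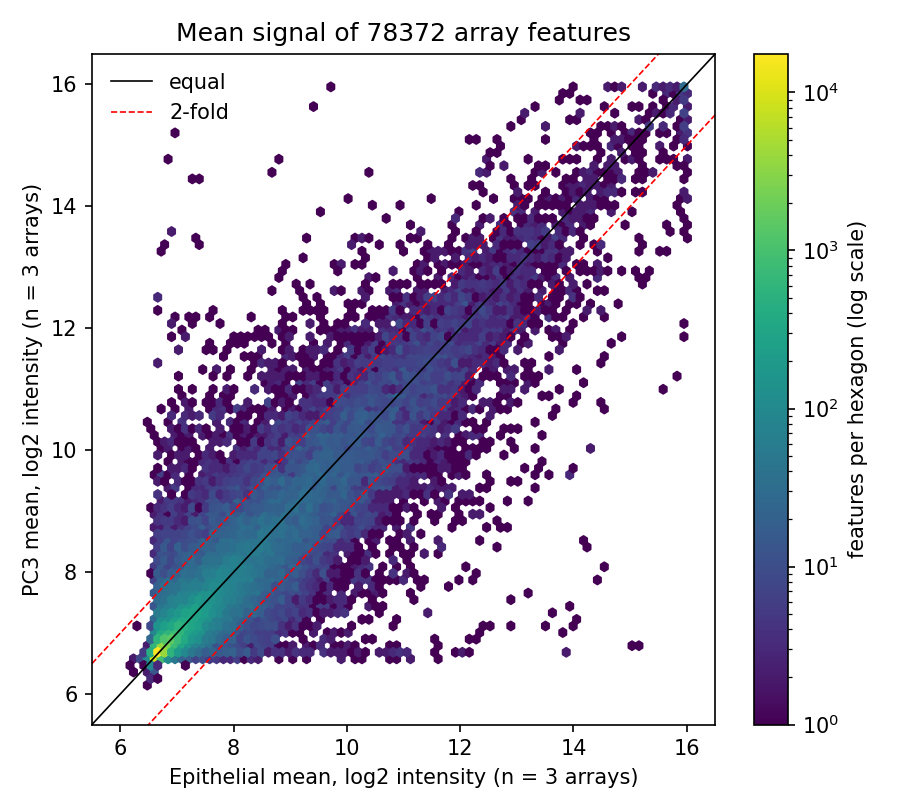
Mean log2 intensity of each feature in PC3 (vertical axis, n = 3 arrays) against normal epithelial cells (horizontal axis, n = 3 arrays), with colour giving the number of features per hexagon on a log scale; the solid line marks equal signal and the dashed lines a 2-fold difference. Most of the 78372 features sit at the lower left end, and 4802 of them passed the test at 2-fold or more, 2448 above and 2354 below the line of equality.

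The share of features that differed was lowest among the dimmest features and highest at a mean between 10 and 12. Of the 38668 features with a mean under 6.8, 11.2% passed the adjusted p and 0 of those changed at least 2-fold. Of the 9267 features between 6.8 and 7, 46.8% passed and 0 changed at least 2-fold. The floor leaves little room for a 2-fold difference in these classes, so the values of 0 reflect it. Of the 16055 features with a mean between 7 and 8, 65.5% passed and 6.895% changed at least 2-fold. Of the 9623 features between 8 and 10, 78.6% passed and 24.5% changed at least 2-fold, with 1207 higher and 1148 lower in PC3. Of the 3428 features between 10 and 12, 81.2% passed and 29.2% changed at least 2-fold, with 482 higher and 519 lower in PC3. Both shares were lower among the 1331 brightest features, with a mean of 12 or more, of which 76.3% passed and 25.5% changed at least 2-fold, with 154 higher and 185 lower in PC3. The median spread between replicates grew from 0.026 to 0.065 log2 units in PC3 and from 0.031 to 0.063 in epithelial cells between the dimmest and the brightest of these classes.

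**Figure D2:**
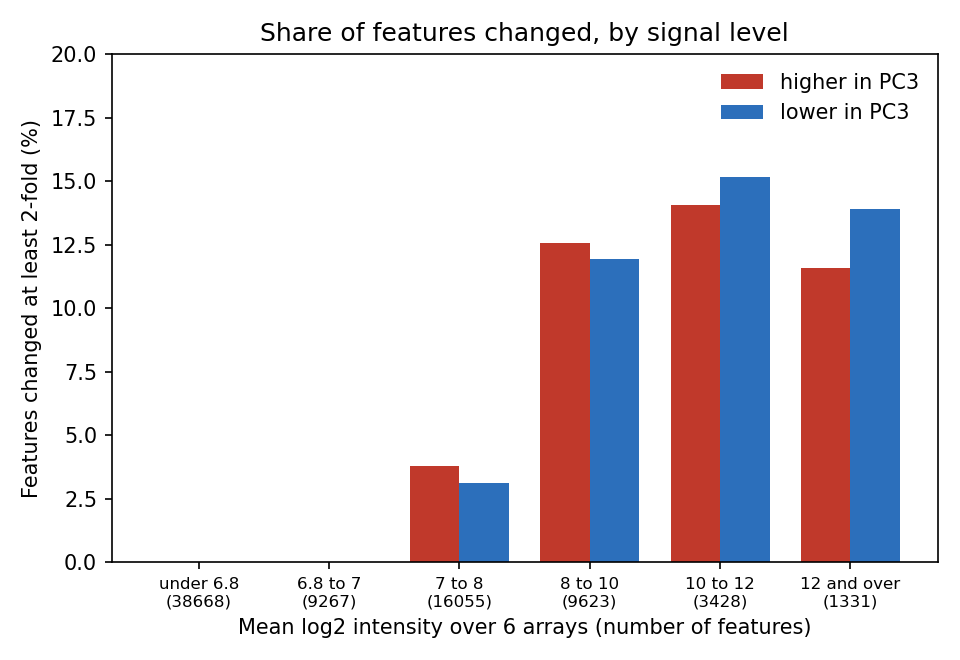
Percentage of features that passed an adjusted p of 0.05 and changed at least 2-fold (vertical axis), by mean log2 intensity over the 6 arrays (horizontal axis, number of features in brackets), for features higher in PC3 (red) and lower in PC3 (blue). Both directions are of similar size at every level, with 12.5% higher and 11.9% lower between 8 and 10, and 11.6% higher and 13.9% lower at 12 and over.

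A small group of features was bright in one cell type and near the floor in the other. With a mean above 8 called bright, 14268 features were bright in PC3 and 14305 in epithelial cells, and 11861 were bright in both. This shared part was 83.1% of the PC3 set and 82.9% of the epithelial set. In PC3 alone, 237 features were bright while the epithelial mean was under 6.9, and 235 of them passed the limma test. In epithelial cells alone, 233 features were bright while the PC3 mean was under 6.9, and 232 of them passed. The median difference was 1.71 log2 units in the PC3 group and -1.76 in the epithelial group. The way these features were selected sets a difference of at least 1.1, so their number rather than their test result is the measurement. With a mean above 10 called bright, 23 features were bright in PC3 alone and 44 in epithelial cells alone. These levels were chosen after the data had been examined, and equal totals of bright features in the 2 cell types follow from the common distribution of the arrays.

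The feature with the largest increase in PC3 was number 42917, at a log2 intensity of 15.26 ± 0.26 in PC3 and 6.94 ± 0.12 in epithelial cells (SD, n = 3 each). Its difference was 8.32 with a moderated standard error of 0.12 (limma, adjusted p = 8.45e-11). The next was number 1783, at 14.71 ± 0.36 in PC3 and 6.84 ± 0.06 in epithelial cells. Its difference was 7.87 with a moderated standard error of 0.15 (limma, adjusted p = 4.03e-10). The moderated standard errors also draw on the spread of features of similar level and do not follow from the printed SDs alone. Both features were higher in PC3 on 3 of 3 arrays, which their selection required. The epithelial values of both lie near the floor, so their fold changes depend on the height of the floor. On the values as deposited they were 319 and 233, and after subtraction of the 1st percentile of each array they were 1366 and 1273.

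Counts of changed features depended on how small differences and the floor were treated. When limma's treat was used to test against a difference of 1.2-fold instead of 0, 13974 features passed, 6858 higher and 7116 lower in PC3, and 4793 of those changed at least 2-fold. When the 1st percentile of each array was subtracted on the linear scale, 11442 features passed the test and changed at least 2-fold, 5736 higher and 5706 lower, against 4802 on the values as deposited. Both settings were chosen after the data had been examined.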

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

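The count of 30534 changed features stayed within 1.5 times under every alternative run except limma's treat against 1.2-fold, which gave 13974, and the count of 4802 features changed at least 2-fold stayed within it except after subtraction of the 1st percentile of each array, which gave 11442; both of these settings were chosen after the data had been examined. The second setting widens folds of features above the new floor and sets features below it in both groups to equal values. Of the 4802 features, 4785 were among the 11442. The replicate block, the fits without a trend or with robust hyperparameters, and treat leave log2 differences unchanged. Leaving out the dimmest features and subtracting neighbours touch only dim features. The 2-fold counts of 4783 to 4807 under these settings were thus largely fixed in advance and do not test the folds. Leaving out 1 array at a time gave 27197 to 31623 changed features and 4760 to 4887 changed at least 2-fold. With the replicate number as a block, 30906 features passed, 29596 of them among the 30534, and 4807 changed at least 2-fold. Deviations of same-numbered arrays correlated by at most 0.095, and not every array correlated best with its own number. Median and 75th-percentile centring moved almost nothing because the arrays already shared 1 distribution, so they test no other scaling. The features bright in 1 cell type alone numbered 23 in PC3 and 44 in epithelial cells when bright was set above 10, against 237 and 233 above 8, and leaving out 1 array gave 232 to 253 and 225 to 235. Features 42917 and 1783 kept their direction and passed the threshold under all alternatives. The filter on negative control probes, the gene-level fit, the mean of a gene's probes, the name classes and the gene lists were not run, as features carry no names. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed features, the real one. It gave 30534 changed features and 4802 at least 2-fold, and the highest of the others gave 0 for both in limma. The other splits had 930 to 2391 features at an unadjusted p under 0.05, against 34991 in the real split. Each of them puts arrays of both cell types in each group, so the difference between cell types widens the spread within groups. Their low counts were thus fixed in advance and lend the real split no weight. In addition, 10 splits are too few for a share under 0.05. The height of the floor limits folds of dim features.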

Other observations

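The tests in this part were chosen after the result had been seen, apart from the fit of PC3 replicate 3 on signal level and the direction of calls near the floor, and the levels that define very bright and dim features were picked after several had been looked at.

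Which group varied more between replicates depended on the measure. The standard deviation was higher among epithelial than among PC3 replicates for 57.5% of the features, most of which are dim. Pairs of PC3 arrays had 40, 151 and 171 features at least 2-fold apart, against 6, 34 and 44 for pairs of epithelial arrays; the counts of 151 and 171 both involve PC3 replicate 3, and the count of 40 without it lies within the epithelial range. Features bright in both cell types made up 88.4% of the PC3 features above a log2 intensity of 7, 76.1% of those above 10 and 73.7% of those above 12.

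Epithelial replicate 3 gave more signal than epithelial replicates 1 and 2 at the features that were very bright in PC3 and dim in epithelial cells. Over the 20 features with a PC3 mean above 12 and an epithelial mean under 7.6 its median lift was 0.098 log2 units, with 14 of 20 lifted and an excess of 0.069% of the PC3 signal, whereas the PC3 arrays had smaller median changes of -0.010 to 0.019 at the 20 features very bright in epithelial cells and dim in PC3, although as many as 15 of those 20 were lifted on PC3 replicate 1. A general lift of dim features on that array is argued against, since 200 features of the same epithelial level that were dim in PC3 had a median change of -0.141 times that lift. Carry-over of PC3 RNA or signal is a candidate explanation, as the linear excess grew with the PC3 level (Spearman's rho = 0.564, permutation p = 0.0111). Pearson's r was 0.41 (permutation p = 0.0707). Without the 2 features farthest from the median, rho was 0.54 and r was 0.45. These p-values do not allow for the choice of this array after its lift had been seen. Carry-over was judged here by growth with the PC3 level. Admixture in PC3 replicate 3 was judged, below, by the size of the change, so the verdicts on these arrays cannot be compared. At the same 20 features, epithelial replicates 1 and 2 had median changes of -0.065 and -0.026 and rho of -0.415 and -0.618. Each array is set against the other epithelial arrays, so these values cannot tell a lift of replicate 3 from low signal on the others. Features of 1 transcript are also not independent, and a difference between epithelial preparations stays open and untested. The 237 features bright in PC3 alone were not lifted as a set (median -0.011, 92 of 237 lifted), which decides nothing, as the same excess would add 0.0032 log2 units there.

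PC3 replicate 3 lay apart from PC3 replicates 1 and 2, with 139 features at least 2-fold from the mean of those arrays. It also lay slightly nearer the epithelial arrays. From single epithelial arrays it differed at least 2-fold at 4762 to 4861 features, against 4905 to 4998 for PC3 replicates 1 and 2. What drew it nearer was not tested over all features. Admixture of epithelial RNA is argued against only at the 20 features very bright in epithelial cells and dim in PC3. Their median change was -0.0125% of the epithelial signal, with a 95% bootstrap interval from -0.046% to 0.0096%. That interval resamples features of 1 array, which may not be independent, and does not cover the spread between arrays. Place on the array is argued against as the whole cause, since the deviation correlated by at most 0.054 between neighbours over all features, and near the floor, where it correlated by 0.269 a row apart, the other 5 arrays gave 0.233 to 0.320. A scaling that depends on signal stays open, since a smooth curve of the level held 0.04% of the variance but the common distribution of the arrays removes such a curve. A difference between cultures, extractions or labellings of PC3 stays open and untested.

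Of the 35816 features near the floor, with both group means under 6.8, 2518 passed the adjusted p of limma, with a median absolute difference of 0.094 log2 units, and 58.5% of them were higher in PC3. An offset between the groups stays open, as the common distribution of the arrays partly fixes this balance. Deviations of these features had a place on the array, since features 199 numbers apart deviated together with r between 0.233 and 0.320 on the 6 arrays, against at most 0.018 for features 300 numbers apart, so that 199 may be the length of a row of the array. Subtracting the mean of the neighbouring dim features lowered the correlation of the differences at a distance of 199 from 0.125 to 0.037. It left 2007 of the 2518 calls (79.7%), which argues against place as the whole cause. Calls near the floor then numbered 3042, so the subtraction also added calls and changed which features passed. Weak binding of abundant transcripts to unrelated probes and small true differences remain open, as the probe sequences were not analysed here.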
